A study of Mus musculus with 2 samples.

How the data were processed

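H3K36me3 ChIP-seq had been done on heart tissue of B6NCrl mouse embryos at embryonic day 13.5, pooled from both sexes, with fragments in a size range of 300 to 500 bp per the labels. Both samples form 1 group with 2 biological replicates, each made of 2 technical replicates, and replicate numbers were taken from the labels. The labels name a separate tissue sample for each replicate but give both the same donor record, so how far apart the replicates are is uncertain.

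The deposited values are peak lists in narrowPeak format on mm10, per the file headers and the listing that came with each sample. Each replicate's peaks were derived from its own filtered alignments and control alignments, with 2 control files for replicate 1 and 1 for replicate 2, per the authors' listing. The pooled list was derived from the alignments of both replicates and both control files, and the replicated list from the pooled list and the replicate lists, per the same listing. The aligner, the peak caller, its threshold and the rule for a replicated peak are not given in the sources used here. For each peak the authors give a signal value, read here as a fold enrichment ratio of ChIP over control, since it lies between 1.31 and 23.0 in all lists. The authors' p-value and q-value for each peak are stored as −log10 p and −log10 q. The smallest −log10 p was 2.03. Of replicate 1 peaks 94.6% and of replicate 2 peaks 92.2% had a q of 0.01 or less. Folds, p and q are the authors' values for single peaks and were used only to describe, rank or filter peaks within a list. Every peak in the replicated list is a row of the pooled list with the pooled values. Read counts were not used here, so library depth is unknown. A deeper library gives more and wider peaks, and the number and length of peaks are therefore not comparable between replicates as amounts of the mark.

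Peaks were compared with the GENCODE annotation, release M21, on GRCm38, the assembly that mm10 denotes. All peaks on the 19 autosomes, X and Y lay within the chromosome lengths of that assembly. Protein-coding genes were kept once per symbol, which left 21829 of 21938. Covered percent is the share of a gene's bases, from annotated start to end, that lie under any peak of a list. A gene was marked when replicated peaks covered at least 20%. Each base of the genome was given to 1 feature in the order promoter (1000 bp either side of an annotated protein-coding start), coding exon, 3' untranslated region, 5' untranslated region, rest of the protein-coding gene body, other annotated gene and intergenic. Profiles along genes used marked protein-coding genes of at least 5000 bp. Exon and intron sets came from the annotated protein-coding transcripts of a gene. A base in any exon of these counted as exon, and the rest of the body as intron, also where another transcript type has an exon. A gene's fold is the mean fold of its replicated peaks weighted by their length within the gene. Domains joined replicated peaks no more than 3000 bp apart. Overlap between replicates was measured as the Jaccard index of covered bases and set beside 100 random placements of 1 list within its chromosomes.

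The gene lists, the threshold of 20%, the summary values and the alternatives were fixed before the data were examined. Of each list the text names up to 4 marked members with the highest mean coverage and up to 3 unmarked members with the lowest, the longer gene first among ties. It also names the 10 marked genes of at least 5 kb with the highest fold, the 5 genes with the largest difference between replicates in each direction and the 5 longest domains. Genes outside this rule are said to be so where they appear, except those given only as a neighbour or an overlapping gene. A list's median coverage was set beside 10000 random lists of protein-coding genes of the same size matched in 20 bins of gene length, separately in each replicate, and its percentile describes these libraries only.

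Alternatives were peaks with q of 0.01 or less, peaks with a fold of at least 3, the pooled list, each replicate alone, 10% and 50% in place of 20% of the gene body, genes of at least 20000 bp, the first exon and intron left out, random lists not matched on length, 50% of a peak in place of 1 bp for a shared peak and equal numbers of the strongest peaks. On simulated peaks the 20% threshold was applied to the mean coverage of 2 lists, not to a replicated list. It recovered 200 of 200 planted genes and called none of the genes of at least 5 kb that touched no planted gene (shorter genes were not checked). Each planted gene held a single long block well above the threshold, so this checks the arithmetic and not the call on many short peaks. Of 20000 intervals 0 differed from a base-by-base count. Of 200 random lists of genes given simulated values without ties, 4.5% lay above the 95th percentile. In the real lists many genes tie without a covered base, so this does not show how the percentiles behave there. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Peaks on scaffolds without a chromosome position were left out of all comparisons.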

Results

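H3K36me3, a methylation of histone H3 that accumulates over the bodies of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing in the heart of B6NCrl mouse embryos at embryonic day 13.5. The series holds 1 group, heart tissue pooled from male and female embryos, with 2 biological replicates that the labels list as separate tissue samples but under the same donor record. No second tissue, stage or genotype is part of the series, so the comparisons lie within the genome: between replicates, between parts of genes, between gene groups and between chromosomes. The measurements are lists of peaks, the intervals in which the authors found more ChIP than control signal. Read totals were not used here, so the depth of each library is unknown and no interval for counting error can be given. Values are the mean ± SD of the 2 replicates unless stated otherwise, and coordinates are those of the mm10 mouse genome. No significance test between groups was run, because there was no second group to test against. Percentiles among random gene lists and intervals over genes describe the spread among genes in these libraries, since genes are not replicates.

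Replicate 1 held 200962 peaks on the 21 chromosomes and replicate 2 held 188592. They covered 167 and 145 Mb, which is 6.12% and 5.33% of the genome (mean 156 Mb ± 15.3, n = 2). The median peak was narrow, 421 bp in replicate 1 and 416 bp in replicate 2, and the longest peaks reached 53913 and 38171 bp. The authors' fold over control had a median of 3.29 and 3.38 and a maximum of 22.5 and 22.1. The authors also deposited a list from both replicates pooled, with 188941 peaks on the chromosomes, and a list of 136494 replicated peaks there, all of which are also in the pooled list. The replicated peaks covered 172 Mb with a median width of 683 bp. A gene is called marked below when replicated peaks covered at least 20% of its body, from annotated start to annotated end.

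The replicates placed the mark over largely the same genes, and their differences lay mostly in how far each gene was covered. Across 21829 protein-coding genes the covered percent had a Pearson r of 0.990 and a Spearman rho of 0.980 between replicates, a correlation across genes, which are not independent. At least 20% of the body was covered in both replicates for 7705 genes, in replicate 1 only for 618 and in replicate 2 only for 68. Among genes of at least 5 kb, the largest excess of replicate 1 was at Purb, a single-strand DNA-binding regulator (42.5% against 13.3% of the body), Gpc2 (39.4% against 14.1%), Aimp2 (73.9% against 48.6%), Wdr81 (68.6% against 43.5%) and Fes, a tyrosine kinase gene (50.3% against 25.5%). The largest excess of replicate 2 was at Asmt, the last enzyme of melatonin synthesis (63.0% against 43.3%), Znhit1 (37.1% against 18.5%), Lat (20.4% against 4.05%), Naa10 (43.2% against 28.9%) and Hypk (45.1% against 32.1%). Gpc2, Naa10 and Hypk lie almost wholly inside or across other protein-coding genes, at 99.3%, 98.5% and 93.3% of their length. With peaks of at least 3-fold mean coverage fell from 27.9 to 14.9% at Purb, from 37.9 to 18.4% at Fes, from 26.8 to 12.4% at Gpc2 and from 27.8 to 14.7% at Znhit1, and the last 2 were no longer marked.

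In bases, the 2 lists shared 127 Mb, a Jaccard index of 68.5%. After 100 random placements of 1 list within its chromosomes the index was 3.31% ± 0.129 (SD over placements) and at most 3.71%. Of replicate 1 bases 76.1% lay in replicate 2 peaks, and of replicate 2 bases 87.4% lay in replicate 1 peaks. By peaks, 71.6% of those of replicate 1 and 86.7% of those of replicate 2 shared at least 1 bp with the other list. Of the strongest peaks by p, 99.99% of 9998 in replicate 1 and 99.99% of 10277 in replicate 2 did so. Coverage was higher in replicate 1 for 7261 marked genes and in replicate 2 for 1141, with a median difference of 4.28 percentage points. All 29 genes of at least 5 kb that differed by 20 points or more had the higher value in replicate 1. The 2 replicate lists were not made against the same number of control files, and replicate 1 was run on a pair of instrument models, so depth, control and biology are not separable in this offset.

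The mark lay in protein-coding gene bodies and was scarce at promoters and between genes. Gene bodies held 94.2% ± 0.207 of covered bases but made up 38.1% of the genome, a 2.47-fold ± 0.00544 (n = 2) excess. Coding exons were the most densely covered feature: 44.4% ± 2.01 of their bases were under peaks, 7.78 ± 0.411 times their share of the genome. Untranslated regions at the 3' end followed at 5.69 ± 0.0996 times, then introns and the rest of the gene body at 2.23 ± 0.0116 times and 5' untranslated regions at 1.63 ± 0.00548 times. Windows reaching 1 kb either side of annotated starts had 0.227 ± 0.000494 times their share. Intergenic sequence, 54.6% of the genome, held 4.74% ± 0.154 of covered bases, 0.0867 ± 0.00282 times its share. Introns held most of the covered sequence, 77.8% ± 0.404 of all covered bases, and make up most of the gene body. Every difference between these features was larger than the difference between replicates.

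**Figure D1:**
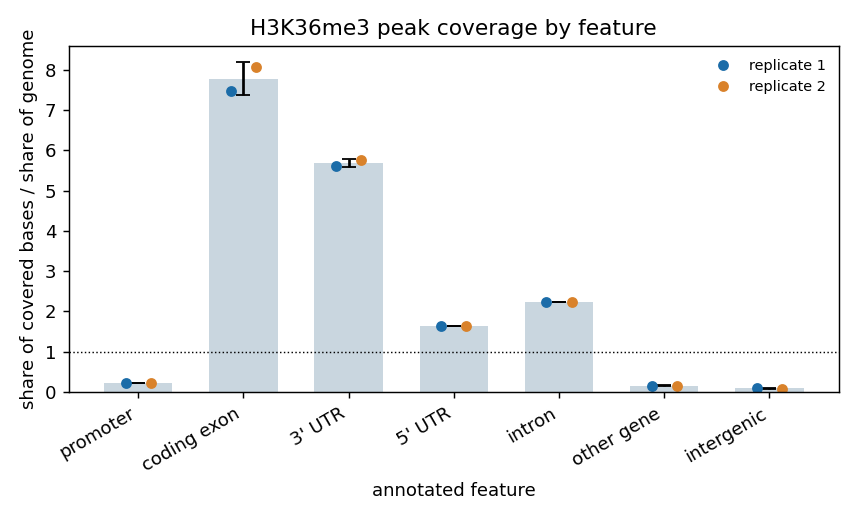
Share of covered bases in each annotated feature divided by the feature's share of the genome, with bars at the mean of the 2 replicates, error bars of 1 SD and a point per replicate. The dotted line marks equal shares. Coding exons stand at 7.78, 3' untranslated regions at 5.69, introns with the rest of the gene body at 2.23, promoters at 0.227 and intergenic sequence at 0.0867.

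Within marked genes coverage was lowest at the start and highest near the end. Over the 7577 marked genes of at least 5 kb, 17.5% ± 1.78 of bases were covered in the first 20% of the gene body, then 45.3% ± 3.50, 58.7% ± 3.73, 67.2% ± 3.77 and 70.0% ± 3.69 (n = 2) in the following steps of 20%. The last 20% was covered 4.01 ± 0.197 times as much as the first 20%, 3.87 times in replicate 1 and 4.15 times in replicate 2. In steps of 5% of the gene body, coverage was 3.22% ± 0.408 in the first step, reached 72.0% ± 3.46 from 90 to 95% and was 65.4% ± 3.74 in the last step. Unmarked genes had 0.845% and 0.666% in the first step and 7.78% and 6.09% in the last, in replicates 1 and 2.

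**Figure D2:**
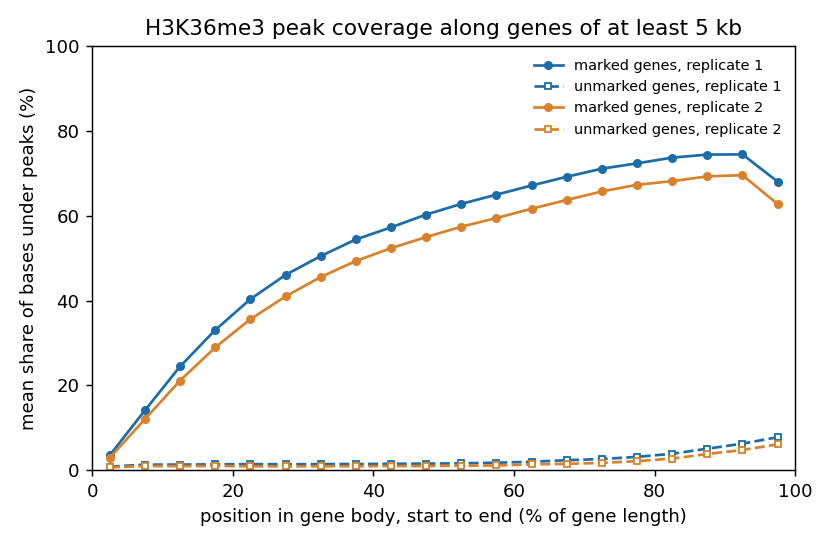
Mean percent of bases under peaks (vertical axis) in 20 equal steps from annotated start to end (horizontal axis, percent of gene length) for marked and unmarked protein-coding genes of at least 5 kb, a line for each replicate. Marked genes go from 3.22% in the first step to 72.0% between 90 and 95% of the body, as means of the replicates.

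Exons of marked genes were covered more than introns of the same genes. Of exonic bases 67.3% ± 3.03 were under peaks, and of intronic bases 42.0% ± 3.54, a ratio of 1.60 ± 0.0631 (n = 2). Both replicates had the same order, 1.56 and 1.65. These ratios pool the bases of all marked genes of at least 5 kb, so long genes, which are mostly intron, weigh most. With each gene weighted equally, a choice made after the data were examined, exons stood at 66.3% ± 2.89 and introns at 48.96% ± 3.34, a ratio of 1.35 ± 0.0335. Compared only within the same twentieth of the gene body, in positions sampled equally from each gene, the ratio was 1.20.

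Replicated peaks marked 8423 of the 21829 protein-coding genes (38.6%), and 9663 genes had no covered base in either replicate. The marked genes of at least 5 kb with the highest mean fold over control were led by Plec, which encodes the cytoskeletal linker plectin (chromosome 15, 76170974 to 76232574; fold 18.4, 40.6% ± 0.905 of the body covered). Next came Zfp68 (fold 17.7, 89.0% ± 1.87), the zinc finger gene Repin1 (17.0, 74.5% ± 0.666), Zfp606 (16.6), Zfp110 (16.4), Zfp27 (16.3), Zfp329 (15.9), Zfp146 (15.8), the mitochondrial RNA polymerase gene Polrmt (15.4, 84.1% ± 2.21) and the collagen galactosyltransferase gene Colgalt1 (15.01, 86.5% ± 0.884). Thus 6 of the 10 belong to the numbered zinc finger genes, whose median fold is given below, and the median over all marked genes of at least 5 kb was 5.17. Repin1 lies wholly within other annotated protein-coding models. Another protein-coding gene overlapped at least 20% of the body for 1021 of the 8423 marked genes, and peaks carry no strand, so coverage there cannot be assigned to either gene. The share marked also differed with gene length: it was 20.98% in the shortest quintile, 36.5%, 50.5% and 51.3% in the next 3 and 33.7% in the longest. Length was not separated here from which genes each quintile holds. Of replicated peaks 95.6% shared at least 1 bp with a replicate 1 peak and 89.0% with a replicate 2 peak, so a marked call does not always rest on both replicate lists.

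Numbered zinc finger genes, a large family of DNA-binding proteins, were marked as a family: 274 of 394, with a median coverage of 36.8% ± 2.39. None of 10000 random lists of as many protein-coding genes of matched length had a median as high in either replicate. Zfp869 (99.2% ± 1.14), Zfp110 (91.4% ± 0.612), Zfp335 (89.2% ± 0.818) and Zfp68 were the most covered. Zfp804b, Zfp936 and Zfp831 had no covered base. The median fold of the 256 marked members of at least 5 kb was 6.29, against 5.15 for 7321 other marked genes of that length.

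Genes of the contractile apparatus carried the mark in these hearts. Of 24 sarcomere genes 19 were marked, with a median coverage of 50.6% ± 1.70 (n = 2). Mybpc3, the cardiac myosin-binding protein C (chromosome 2, 91118144 to 91136516), was covered over 91.3% ± 2.95 of its body. The giant spring protein gene Ttn stood at 84.8% ± 1.299, the tropomyosin gene Tpm1 at 82.3% ± 0.773 with a fold of 10.7, and the cardiac troponin T gene Tnnt2 at 80.4% ± 6.98. The 5 unmarked members were Myom2 and Tcap at 0, the myosin light chain genes Myl7 (9.60% ± 6.00) and Myl3 (12.6% ± 0.529), and Nebl (14.5% ± 0.792), the last 2 named after their values were seen. Among 10000 length-matched random lists, 3 in replicate 1 and 1 in replicate 2 had a median as high as the sarcomere list, and the typical random median was 5.30% and 3.37%. Another protein-coding gene overlapped 4 of the members by at least 20%. Without these 15 of 20 were marked.

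Genes of cardiac excitation and calcium handling were marked in part. Of 19 members 11 were marked, the median coverage was 21.97% ± 4.39, and the median lay at the 99.4th and 99.04th percentile of random lists in replicates 1 and 2. The calcium pump gene Atp2a2 (chromosome 5, 122453513 to 122502225) stood apart at 90.4% ± 0.517. The potassium channel gene Kcnh2 had 51.3% ± 0.866, the junctophilin gene Jph2 36.5% ± 0.616 and Kcnj2 29.4% ± 9.28. The atrial potassium channel gene Kcnj3 had none, the pacemaker channel gene Hcn1 0.0426% ± 0.0602 and Trdn 1.102% ± 0.249. With peaks of at least 3-fold alone, 7 members were marked.

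Of 22 cardiac transcription factor genes 12 were marked, with a median of 20.4% ± 1.55 at the 91.6th and 96.9th percentile. Gata6 had 79.2% ± 5.84 of its body covered, the T-box genes Tbx20 74.0% ± 2.32 and Tbx5 62.2% ± 4.95, and the serum response factor gene Srf 55.9% ± 0.306. Pitx2, a left-right patterning gene of the atria, Isl1, a gene of cardiac progenitors, and Hey1 had no covered base. Of 8 ventricular genes 4 were marked: Myh7, the beta myosin heavy chain (68.4% ± 0.201), Hey2 (49.8% ± 4.98), Myl2 (41.7% ± 0.186, with 43.4% of its body overlapped by Ccdc63) and Irx4 (20.7% ± 1.76). Irx4 was not marked with the replicate 1 list alone (19.5%) or with peaks of at least 3-fold, where its mean coverage was 11.99%. Lrrc10 and Nppb had none, Mpped2 had 10.5% ± 2.89 and the fourth unmarked gene was Myl3. Of 10 atrial genes only Myl4 was marked, at 18.4% ± 0.0815 in the replicates and at least 20% in the replicated list. It was not marked with either replicate list alone. Bmp10, Sln and Kcnj3 had none, nor did Nppa, which lies outside the naming rule. Nppa (1.36 kb), Nppb (1.42 kb) and Lrrc10 (1.43 kb) are short, as is the sarcomere gene Tcap (1.14 kb). Genes under 3 kb were seldom marked (16.5% with an intron and 2.65% without, in the sets counted below). A value of 0 at these genes therefore does not show that they were silent. The medians of the 2 chamber lists lay at the 72.5th and 79.9th (ventricular) and the 53.3rd and 53.2nd (atrial) percentile, and the difference between the lists was not tested.

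**Figure D3:**
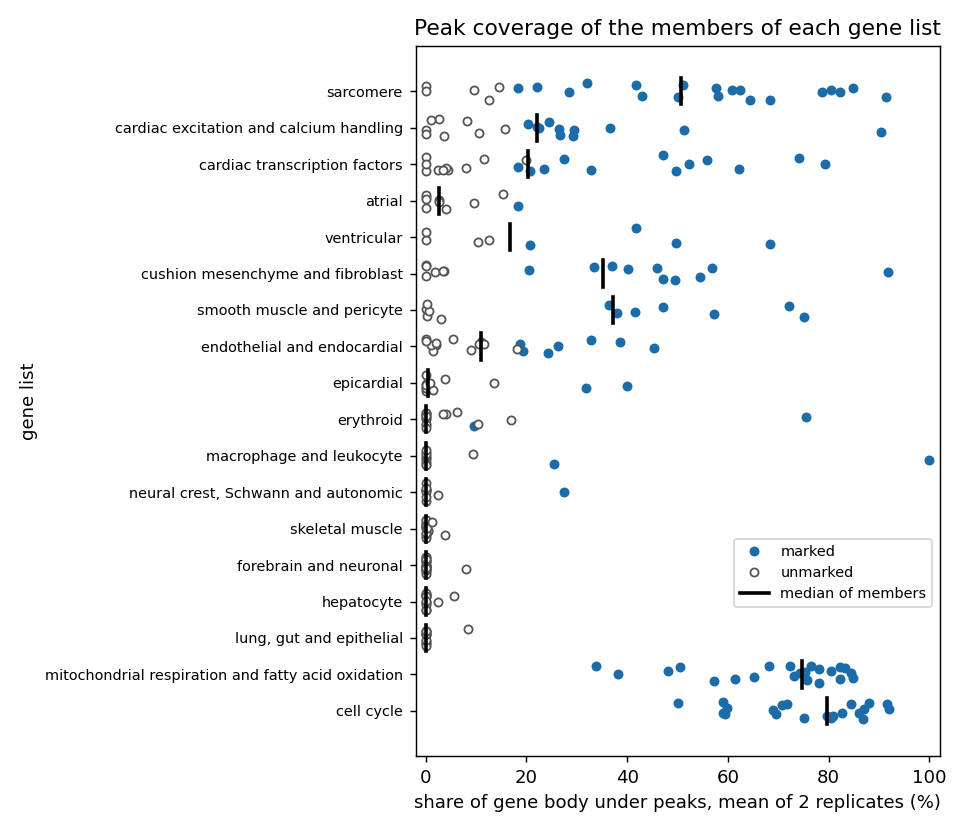
Percent of the gene body under peaks, as the mean of the 2 replicates (horizontal axis), for each member of 18 gene lists (vertical axis), with filled points for marked and open points for unmarked genes and a bar at each list's median. Sarcomere genes have a median of 50.6%, cell cycle genes 79.1% and mitochondrial genes 74.4%, while the skeletal muscle, forebrain, hepatocyte and lung and gut lists hold no filled point.

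Of 16 genes of cushion mesenchyme and fibroblasts, the cells that build valves and connective tissue, 10 were marked, with a median of 35.2% ± 7.45 (99.4th and 98.3rd percentile). Fibronectin, Fn1 (chromosome 1, 71585520 to 71653200), led with 91.8% ± 1.90, ahead of the collagen genes Col1a1 (56.8% ± 5.15) and Col1a2 (49.6% ± 5.40) and the proteoglycan gene Vcan (54.5% ± 4.60). The short transcription factor genes Tcf21 and Twist1 had no covered base, nor did Scx, which lies within Bop1. Of 12 smooth muscle and pericyte genes 7 were marked (median 37.2% ± 5.64, 97.3rd and 96.2nd percentile). Cnn1 had 75.1% ± 4.52, Smtn 72.0% ± 3.05, Acta2 57.3% ± 0.453 and Myocd 47.1% ± 1.31. The 5 unmarked ones included Myh11, the smooth muscle myosin gene, at 0.137% ± 0.194, Lmod1 at 0.227% ± 0.320 and Rgs5 at 0.249% ± 0.353. The other 2, named after their values were seen, were Mylk at 0.687% ± 0.0794 and Kcnj8 at 3.11% ± 4.40.

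Endothelial and endocardial genes did not stand apart from random lists of matched length. Of 19 members 7 were marked, among them Eng (45.3% ± 3.91), Notch1 (38.5% ± 3.51), the growth factor receptor gene Kdr (32.7% ± 9.13) and Nfatc1 (26.3% ± 7.56). The median was 10.9% ± 3.27, at the 64.3rd and 59.3rd percentile. With the replicate 2 list alone 4 were marked, and with peaks of at least 3-fold 4. With those peaks the mean coverage of Kdr was 16.9%, though replicated peaks still marked it, and Nfatc1 was unmarked at 18.03%. Sox17 and Sox18 had none and Erg 1.04% ± 0.594. Of 12 epicardial genes 2 were marked, the keratin gene Krt18 (40.02% ± 7.68) and Tbx18 (31.9% ± 6.86), while Upk1b, Lrrn4 and Upk3b had none. Mean coverage of Krt18 was 17.4% with peaks of at least 3-fold, though replicated peaks still marked it.

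Genes of blood cells and of nerve and glial cells were mostly unmarked. Of 17 erythroid genes 2 were marked, the transferrin receptor gene Tfrc (75.5% ± 2.58), which dividing cells of many kinds express, and Epor, which had 19.1% in replicate 1 and 0 in replicate 2 and was marked with neither list alone. With the replicate 2 list alone 1 erythroid gene was marked. Gata1, Slc4a1 and Gypa had no covered base. Of 12 macrophage and leukocyte genes 2 were marked. Cd68, 1.94 kb long, was covered over its whole length in both replicates and lies beside the widely expressed Eif4a1. Cx3cr1 had 25.4% ± 0.168, and 53.2% of its annotated body is overlapped by Xirp1, Csrnp1 and other genes. Adgre1, Ptprc and Fcgr1 had none. Of 10 neural crest, Schwann and autonomic genes the receptor gene Erbb3 alone was marked (27.4% ± 5.35), and Stmn2, Ret and Th had none. These lists also hold genes under 3 kb, among them the globin genes, which lie outside the naming rule and had no covered base. Such short genes were seldom marked (16.5% with an intron and 2.65% without, in the sets counted below). Missing peaks there therefore do not show that the genes were silent.

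Genes of other organs were unmarked. None was marked of 20 forebrain and neuronal genes, of which Grin2b, Rbfox3 and Gad2 are the longest without a covered base. The same held for 16 hepatocyte genes (Apoh, Hnf4a, Apob), 13 lung, gut and epithelial genes (Trp63, Cdh1, Epcam) and 18 skeletal muscle genes (Ryr1, Pax7, Pax3). No gene was marked among 1133 olfactory receptor, 328 vomeronasal receptor, 39 Hox or 67 clustered histone genes, and only Krt18 among 53 keratins. The olfactory receptor gene Olfr56, the vomeronasal receptor gene Vmn2r7, the Hox gene Hoxc5 and the histone gene Hist1h2bc, each the longest of its family without a covered base, stand for these. Lists with a median of 0 tie with many random lists, so their percentiles say little. The clustered histone genes are short, with a median length of 0.539 kb. Among genes under 3 kb without an intron, counted below without these receptor and histone families, 20 of 756 were marked (2.65%). Missing peaks therefore do not show that histone genes or other genes under 3 kb in these lists were silent.

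Genes of general cell functions were marked nearly throughout. All 22 genes of mitochondrial respiration and fatty acid oxidation were marked (median 74.4% ± 1.07), led by Uqcrc1 (84.8% ± 0.735), Atp5b (84.5% ± 1.00), Uqcrc2 (83.3% ± 2.34) and Acadvl (82.2% ± 0.0676, with 40.5% of its body overlapped by Dvl2). All 21 genes of transcription, splicing and translation were marked (median 74.7% ± 1.15), among them the spliceosome genes Snrnp200 (93.3% ± 1.78) and Prpf8 (92.1% ± 0.628), the elongation factor gene Eef2 (86.0% ± 2.10) and Polr2b (84.8% ± 0.437). So were all 21 cell cycle genes (median 79.1% ± 1.51), with Top2a at 92.0% ± 1.34, Mcm5 at 91.5% ± 0.738, Mcm2 at 88.0% ± 1.47 and Cdk1 at 87.0% ± 0.918. Of 77 ribosomal protein genes 70 were marked (median 60.3% ± 1.14). Rps15a had 89.8% ± 0.287, Rps5 81.8% ± 3.63, Rps28 80.5% ± 2.48 with 70.3% of its body overlapped by Kank3, and Rpl5 79.8% ± 2.04. Rpl3l, Rpl39l and Rpl10l, named for their likeness to other ribosomal protein genes, had none. No random list reached the median of these 4 lists in either replicate.

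Of 15 genes that write, erase or read H3K36 methylation 13 were marked (median 62.8% ± 3.56, above all random lists). The demethylase gene Kdm4a had 92.2% ± 0.144, Psip1 80.3% ± 0.970 with 39.0% of its body overlapped by Snapc3, Brpf1 78.3% ± 4.79 and the methyltransferase gene Nsd1 77.8% ± 2.02. Phf19 (5.04% ± 1.65) and Kdm2b (16.0% ± 2.56) were unmarked, though Kdm2b was marked with the pooled list (21.2%). Of 14 imprinted protein-coding genes 8 were marked (median 29.5% ± 5.85, 92.5th and 89.2nd percentile). Igf2r had 90.3% ± 2.26, Impact 71.2% ± 4.13, Peg3 66.9% ± 6.93 and Grb10 58.2% ± 1.29, while Dlk1, Magel2 and Cdkn1c had none. Of 56 clustered protocadherin genes 21 were marked. Pcdhga3 (49.6% ± 3.85), Pcdhga2 (49.3% ± 4.16), Pcdhgb1 (48.998% ± 3.57) and Pcdhga4 (48.5% ± 3.83) were highest, and Pcdha1, Pcdha2 and Pcdha3 had none. Each of the 56 is overlapped by another protein-coding gene model over at least 20% of its body, so these values are not independent.

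Joining replicated peaks no more than 3 kb apart gave 25434 domains with a median length of 3.32 kb. The 6954 domains of at least 10 kb held 81.0% of covered bases, and 53 were at least 100 kb long. The longest ran from 76678358 to 76955318 on chromosome 2, 277 kb over Ttn and its neighbour Plekha3, with 87.8% of bases covered in replicate 1 and 85.2% in replicate 2. It was followed by 203 kb over the fibrillin gene Fbn2 (chromosome 18, 58005596 to 58208560), 194 kb over Syne2 (chromosome 12, 75876940 to 76070884), 166 kb over Usp34 and Ahsa2 (chromosome 11, 23330424 to 23496584) and 164 kb over Fry (chromosome 5, 150334306 to 150498571).

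**Figure D4:**
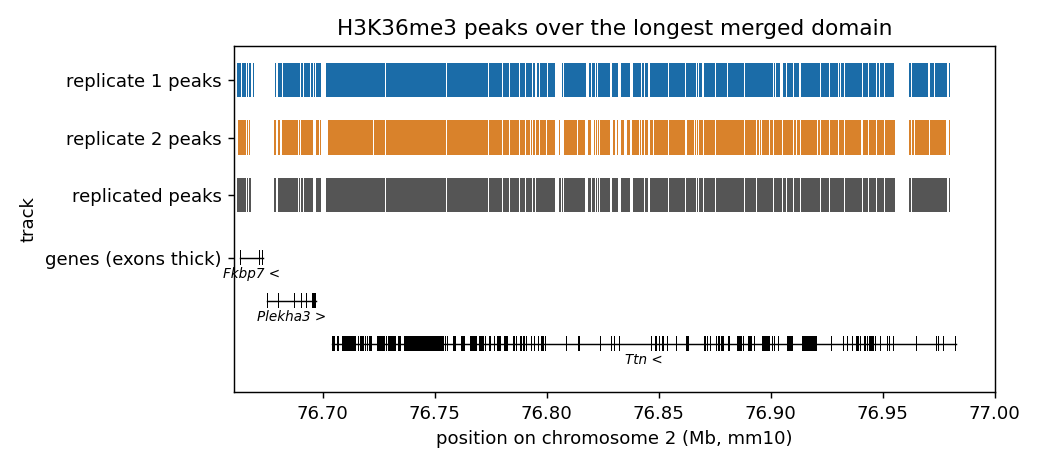
Peaks of each replicate and replicated peaks (coloured blocks) above protein-coding gene models with exons as thick blocks and the direction of transcription as an arrowhead, on chromosome 2 from 76660359 to 77000318 (horizontal axis, Mb, mm10). Peaks cover 85.7% and 83.9% of Ttn in replicates 1 and 2 and leave its start, at the right, uncovered.

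Genes on the X chromosome were covered less than autosomal genes. Over X-linked protein-coding gene bodies 4.41% ± 0.722 of bases were under peaks, against 14.8% ± 1.39 on autosomes, a ratio of 0.297 ± 0.0208 (n = 2). The ratio was 0.311 in replicate 1 and 0.282 in replicate 2. Of 948 X-linked genes 157 were marked (16.6%), and of 20698 autosomal genes 8266 (39.9%). Every autosome lay above X, from 11.2% ± 1.09 on chromosome 14 to 20.0% ± 1.67 on chromosome 11. Of 183 genes on Y none was marked. The tissue came from both sexes in a proportion that the labels do not give, so X had fewer copies than autosomes in part of the cells, and Y in all of them.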

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

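The tests on shared zinc finger sequence, on the upper end of fold and on escape genes were chosen after the result was seen, and the others before. The series holds 1 group, so no biological explanation based on groups was tested. Intervals over genes hold for these libraries only.

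Outside the chromosomes, 22 replicated peaks lay on scaffolds that no comparison used: 13 on a scaffold assigned to X, 4 on scaffolds assigned to chromosome 4 and 5 on a scaffold of unknown place. Signal in unused data is what marked them for a second look.

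Numbered zinc finger genes made up 6 of the 10 genes of at least 5 kb with the highest fold, which sequence shared between family members or base composition could produce. In the peaks of all 256 marked members of at least 5 kb, 98.1% of 50-base words occurred once in the genome. In as many other marked genes 98.7% did. Of the members 90.6% had at least 95% such words, and the 5th percentile over members was 92.3%. Words were taken only from called peaks and compared by exact match, and the genes of highest fold were not searched apart. For most members this argues against exactly repeated sequence as the cause, if reads were at least that long. It does not address copies that differ by a few bases. Within bins of GC content the median fold of the zinc finger genes was 1.21 times that of other marked genes (1.16 to 1.32 over 95% of resampled genes), hardly below the 1.22 before matching. The bound set in advance for excluding GC content lay above the unmatched ratio, so this test alone decides nothing. At the upper end, 16.8% of the members (43 of 256, exact binomial interval 12.4 to 21.95%) lay above the 99th percentile of other genes in their GC bin. That argues against GC content there, and a property of these genes themselves stays open as a hypothesis. Both intervals count members as independent and may be too narrow, since members can be neighbours. Zfp606, Zfp329 and Zfp110 lie near each other on chromosome 7, and so do Zfp27 and Zfp146.

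Exons were covered more than introns, which could come from the place of introns in the gene or from base composition. In positions sampled equally from each gene the ratio was 1.35 ± 0.0358. Within the same bins of GC content of the surrounding 1 kb it was 1.42 ± 0.0337, so GC content at that scale does not account for it. The mean GC content at that scale was 48.1% around exon positions and 45.7% around intron positions. The GC content of the exons and introns themselves was not matched, so it is not excluded. Within the same twentieth of the gene body the ratio was 1.20 ± 0.0234, so position accounts for part of the difference. The rest could be position at a finer scale, a difference between exons and introns or a property not measured here. These cannot be told apart, since the value lies between the bounds set in advance for position as the cause or not.

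X-linked genes were covered 0.297 times as much as autosomal genes, which could reflect which genes X carries, fewer X copies to sequence, or the silencing of an X chromosome in female cells. That value pools bases. With each gene weighted equally the ratio over all genes was 0.351 ± 0.0204. Over 22 families of general cell functions found on both (44 X-linked and 548 autosomal genes) the ratio, also with equal weights, was 0.586 ± 0.0165, with an upper end of 0.747 and 0.722 over resampled genes in the replicates. Gene content thus may account for part of the difference, and whether it accounts for all of it cannot be told. The families were taken by symbol and not matched on expression. Their X-linked members include genes with no covered base such as Usp26 and Taf7l, named after their values were seen. If the fold is scaled by the control at each place, fewer copies would lower ChIP and control alike and leave it near that of autosomes. The fold of marked X members was 0.706 times the autosomal one (0.631 to 0.811 over 95% of resampled genes). How the fold was scaled is not given, so this value cannot exclude fewer copies. Fewer X copies and X inactivation both stay open as hypotheses.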

How the results depend on the processing

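Of 35 alternative values for the main results with both replicates kept, 19 stayed within the spread between replicates, within 1 point for the overlap or within 1.5 times for counts, and none turned round a direction. A mean of 2 replicates lies within their SD of each, so leaving out a replicate could not move most values past it and is given as a range only. With each replicate left out, genes were also called marked from the remaining list alone. The values then ranged from 2.466 to 2.474 for the gene body excess, 3.85 to 4.10 for the ratio of the last to the first 20% of the gene body and 1.549 to 1.553 for exons to introns. They ranged from 0.282 to 0.311 for X to autosomes, 49.4 to 51.8% for the sarcomere median and 7773 to 8323 for marked genes. On the genes marked by the replicated list, exons to introns stood at 1.56 in replicate 1 and 1.65 in replicate 2, so that ratio also moved with the gene set. The pooled list, which has wider peaks, gave 2.46, 3.57, 1.54 and 0.331 for the 4 ratios in that order and 58.1% for the sarcomere median. Peaks of at least 3-fold gave 2.48 for the gene body excess, 4.49 for last to first 20%, 0.261 for X to autosomes and 48.0% for the sarcomere median. Genes of at least 20 kb gave 3.0 for last to first 20% and 1.68 for exons to introns, and the latter was 1.496 without the first exon and intron. Requiring 50% of the gene body left 5046 marked genes, and requiring 50% of a peak lowered the share of peaks found in the other replicate from 79.2 to 70.5%. Alternatives chosen after seeing the data were equal weight per gene, with 1.35 for exons to introns, sarcomere genes without overlapped members, with a median of 54.4%, the 7705 genes covered in each replicate and the 7402 marked genes not overlapped by another. Apart from limits set by construction (fewer peaks, fewer genes or other weights), the cause was not tested. Of 203 counts of marked genes per list 176 stayed within 1.5 times, and 15 of the 27 others came from requiring 50% of the body. Of 486 values for named genes with both replicates kept 370 stayed within their spread, and 70 of the rest came from the pooled list. No paired analysis was possible because the series holds 1 group. Depth is unknown, so a gene without peaks may carry the mark below what these libraries could detect, and with 10 in place of 20% of the body 9590 genes were marked.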

Other observations

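The test on escape genes was chosen after its values had been seen, and all genes in this part lie outside the rule for named genes and were chosen after seeing the data or from general knowledge of them.

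Several noncoding RNA genes carried the mark. Outside protein-coding bodies, 87 of 5358 long intergenic noncoding RNA genes were covered over at least 20% (1.62%). The share was larger for microRNA genes, with 94 of 916 (10.3%), and for small nucleolar RNA genes, with 49 of 968 (5.06%). These classes were not matched on gene length, and genes inside other noncoding genes were kept. The shares are therefore not comparable between classes as a frequency of the mark. In the imprinted cluster on chromosome 12, where the protein-coding Dlk1 had no covered base, the noncoding Meg3 (109541001 to 109571726) had 54.0% ± 10.6 of its body covered, Rian 30.4% ± 5.65 and Mirg 59.5% ± 1.23 (SD, n = 2). H19, another imprinted RNA gene, had 35.7% ± 10. Malat1 on chromosome 19 (5795690 to 5802672), a 6.98 kb RNA gene of the nucleus, had 66.5% ± 1.17, and its neighbour Neat1 had 1.91% ± 0.0340. Airn, which overlaps Igf2r, had 41.9% ± 1.71, with 39.9% of its length in protein-coding bodies, and Mhrt, antisense to Myh7, had 65.3% ± 1.88 with 64.6% inside, so peaks there cannot be assigned to a strand. Around the X inactivation centre Ftx had 31.3% ± 0.238, Jpx 12.9% ± 0.669 and Xist 10.5% ± 5.05, with 93.2% of Xist inside annotated protein-coding bodies. Of noncoding RNA genes known from heart, Fendrr, which lies wholly inside a protein-coding body, had no covered base, Bvht had 5.01% ± 0.437 and Carmn 14.03% ± 1.76.

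Of 25434 domains 636 (2.501%) touched no annotated gene, and 4 of these were at least 10 kb long. The longest spanned 16.5 kb on chromosome 5 (104581010 to 104597554), with 56.0% and 47.4% of its bases covered in replicates 1 and 2. Short genes with and without an intron were counted apart, with no test of the difference. Under 3 kb and away from other protein-coding genes, and without the olfactory, vomeronasal and histone families, 148 of 899 genes with an intron were marked (16.5%), and 20 of 756 without (2.65%).

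A hypothesis for the lower fold on X, 0.706 times that of autosomes over the same families, is X inactivation in the female part of the tissue, which genes known to escape it avoid. Kdm5c, Kdm6a, Eif2s3x and Ddx3x, which are known to escape in mouse, had folds of 6.37, 4.54, 9.09 and 6.95. Their median of 6.66 stood at percentile 100 among 10000 random sets of 4 out of 325 X-linked genes with replicated peaks. The genes were chosen after their folds had been seen, so this value decides nothing. They also are widely expressed, and strong expression alone could give the same value. Kdm6a, covered over 11.5% ± 0.542, was itself unmarked.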
